A study of Mus musculus with 9 samples.

How the data were processed

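Neuro2a cells, a mouse neuroblastoma line, had been treated for 48 h with a control siRNA (siControl), an siRNA against Myt1 (siMyT1) or an siRNA against Kdm1a, the gene of the histone demethylase LSD1 (siLSD1), with 3 arrays per group and 9 in all. Per the labels, total RNA was extracted with a column kit and labelled with biotin for a 1-colour array. The deposited values are intensities on a linear scale, with 1 value for each of 45101 probe sets on each array. The summarisation, background and scaling steps behind these deposited intensities are not given in the sources used here. No percentile, trimmed mean or control probe set was equal on all arrays, so what 1 unit stands for stays unknown. Array medians lay between 0.302 and 0.424 units and summed intensities between 196271 and 219953 units, and 48 values over all arrays were 0. The labels do not say whether the replicates of a group came from separate cultures, so p-values measure the spread between these samples only, which may be technical. For arrays, the number of samples limits the precision.

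Probe sets were named from the annotation table of the array platform. It listed 35890 probe sets, of which 932 had several gene symbols and 34945 had 1 symbol after the control probe sets were left out, and 9211 probe sets, controls included, were not listed and are unnamed here. Entrez identifiers of 34741 single-symbol probe sets matched the RefSeq gene table of assembly GRCm38.p6, which was used for names only and changed 0 symbols. No coordinates are given, because no genome build is tied to the array. Each gene was represented by the probe set with the highest mean over all arrays, which gave 18193 genes, 9010 of them with more than 1 probe set. Among called genes with other probe sets, a second probe set was called in the opposite direction for 5 of 810 in siMyT1 against siControl, 6 of 1036 in siLSD1 against siControl and 27 of 2144 in siMyT1 against siLSD1. A gene that the rule for named genes includes but that has no named probe set is not reported here.

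Values were analysed as log2(value + pseudocount). The pseudocount had been fixed in advance at 32 for linear intensities, without a stated mean intensity. Because the array medians proved far below 32, all values were referred to a larger scale by 1 constant for all arrays, 163.6. This constant, chosen after the values were seen, sets the mean over arrays of the intensity mean, trimmed by 2% at each end, to 500. The pseudocount is then 0.196 deposited units. Fold changes are on this log2(value + pseudocount) scale and understate the change of dim genes. Array medians differed by under 0.5 on the log2 scale, and the values were therefore used as deposited, without a further normalization between arrays.

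Differences were tested with limma 3.58.1 in R 4.3.3 by a linear model of group means over all 9 arrays, moderated with an intensity trend, with 6 residual and 6.83 prior degrees of freedom. All tests were two-sided, and p-values were adjusted over all genes by the Benjamini-Hochberg method with a threshold of 0.05. The 3 comparisons were siMyT1 and siLSD1 against siControl, and siMyT1 against siLSD1, with an F-test over the 3 groups. With 3 arrays against 3, an exact permutation test of a single gene could not go below p = 0.1, so all p-values come from limma. The script was tested on simulated arrays for the same 18193 genes. In siMyT1 against siControl it recovered 57% of genes changed 1.5-fold and 89% of genes changed 2-fold, with 6 unchanged genes called. In siLSD1 against siControl the values were 52%, 92% and 7.

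Before the data were examined, 22 gene lists were fixed and tested in each comparison, 66 tests in all, with camera at a preset correlation between genes of 0.01, and adjusted together. They were run again with an estimated correlation. Beside camera, fry tested whether the members of a list moved on balance in 1 direction or changed in either direction. The fry results below are those for 1 direction unless said otherwise. The members past the threshold were counted after adjustment over all genes and adjusted over the list alone. Overlaps and the correlation between the knockdowns were set beside 100 simulations of unchanged groups against the same control arrays. The rule for named genes, also fixed in advance, took the siRNA targets with every probe set, the 10 largest rises and 10 largest falls per comparison among called genes whose arrays did not overlap between groups (with unnamed clones replaced by the next named gene), up to 4 members per list with the smallest adjusted p, and the 10 genes per direction with the largest smaller change in the overlap of the knockdowns. Genes named outside it are said to be so.

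Alternatives fixed in advance were quantile normalization, median centring of each array, pseudocounts of 1 and 100, a filter on dim probe sets, other treatments of probe sets, fits of the compared groups alone, other variance models, array weights, the replicate number as a block, a 1.5-fold threshold, and leaving out each array in turn. A pseudocount of 32 added to the deposited units is the literal form of the rule fixed in advance. It became an alternative, not the main setting, only after the data were seen. So did a floor of 0.01 units, which the rule had named for ratios. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.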

Results

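Gene expression was measured on 9 arrays of Neuro2a cells, a mouse neuroblastoma line of neural crest origin, 48 h after treatment with siControl, siMyT1 or siLSD1, with 3 arrays in each group. Myt1 is a zinc finger transcription factor of the developing nervous system, and LSD1, the product of Kdm1a, removes methyl groups from histone H3 lysines as part of complexes with CoREST proteins and histone deacetylases. The series concerns Myt1 as a member of a neural LSD1 complex, and the comparisons ask which transcripts change on loss of either protein and how far both sets of changes coincide. Log2 values correlated at 0.992 to 0.994 between arrays of a group and at 0.986 to 0.992 between arrays of different groups. All adjusted p-values below are from limma unless a list test is named, and levels are means ± SD over 3 arrays in deposited intensity units.

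Each siRNA lowered its own target and not the other. Myt1, by its brighter probe set, measured 4.90 ± 0.34 in siControl and 0.660 ± 0.21 in siMyT1, or 13.5% of control (log2 fold change -2.60, SE 0.15, adjusted p = 1.25e-06). In siLSD1 it measured 6.95 ± 0.72, a difference from control that did not pass the test (log2 fold change 0.49, adjusted p = 0.0645). The other Myt1 probe set was dim in all groups, at 0.0605 ± 0.045 units in siControl. Kdm1a, by its brighter probe set, measured 29.0 ± 1.0 in siControl and 4.49 ± 0.40 in siLSD1, or 15.5% of control (log2 fold change -2.64, SE 0.07, adjusted p = 3.04e-10), against 30.9 ± 1.6 in siMyT1 (adjusted p = 0.547). Its other probe set measured 14.5 ± 0.46 in siControl and 1.10 ± 0.17 in siLSD1, or 7.59% of control.

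**Figure D1:**
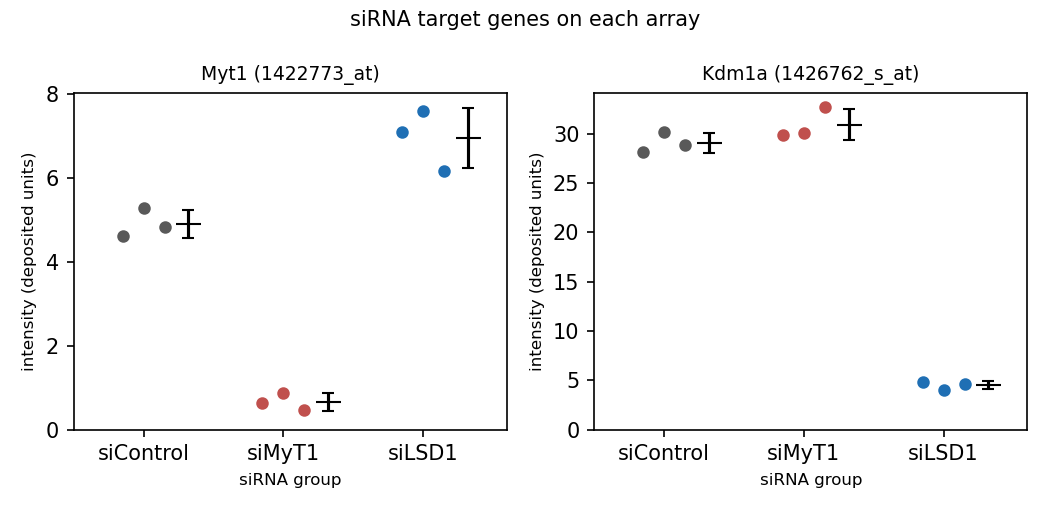
Intensity of Myt1 (left) and Kdm1a (right) in deposited units on each of the 9 arrays, by siRNA group; points are arrays, and the bar beside them is the mean with its SD over 3 arrays. Myt1 lay between 0.474 and 0.882 on the siMyT1 arrays and between 4.60 and 5.27 on the siControl arrays, and Kdm1a between 4.05 and 4.80 on the siLSD1 arrays and between 28.1 and 30.1 on the siControl arrays.

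After siMyT1, more members fell than rose in the lists of neuronal, neuroblastoma lineage and cholesterol genes, and more rose than fell among mesenchymal markers. Camera called these 4 lists, and none of the calls held with an estimated correlation (adjusted p = 0.876, and 0.879 for the neuroblastoma list, with an estimated correlation). Of 38 measured members of the list of neuronal genes of the type repressed by REST outside neurons, 9 fell and 1 rose. The falls included the granins Chgb (log2 fold change -0.71, SE 0.06, adjusted p = 3.16e-05) and Chga (-0.43, SE 0.08, adjusted p = 0.00512), which are matrix proteins of dense-core vesicles, and Celsr3, an atypical cadherin of axon tracts (-0.43, SE 0.07, adjusted p = 0.00227). Rab3c, a small GTPase of synaptic vesicles, rose by 0.52. Of 22 neuroblastoma lineage genes, 6 fell and 1 rose. Those that fell included Hand2 and Phox2a, transcription factors of sympathetic neurons (-0.46 and -0.33), Slc18a2, the vesicular monoamine transporter (-0.35), and Chrna3, a nicotinic receptor subunit of ganglia (-0.52). Adjusted over the list alone, 11 neuronal members were lower and 1 higher, and 10 neuroblastoma members were lower and 2 higher.

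In the cholesterol synthesis and uptake list, 6 of 20 members fell after siMyT1 and 0 rose, or 11 lower and 1 higher adjusted over the list alone. Srebf2, the transcription factor that drives the pathway, fell from 16.7 ± 2.0 to 9.26 ± 0.72 (log2 fold change -0.83, SE 0.12, adjusted p = 0.00134). The enzymes Idi1 (-0.57, adjusted p = 0.00189), Dhcr7 (-0.52, adjusted p = 0.00441) and Cyp51 (-0.39, adjusted p = 0.0159) fell with it, although the call for Cyp51 was lost when siControl replicate 1 or 3 or siMyT1 replicate 2 was left out (adjusted p up to 0.0581). Among 22 mesenchymal and fibroblast markers, 5 rose and 0 fell, also when adjusted over the list alone. Sparc, a collagen-binding matrix protein, rose from 12.4 ± 0.54 to 32.8 ± 1.6 (log2 fold change 1.39, SE 0.07, adjusted p = 6.41e-07). Fn1, which encodes fibronectin, rose by 0.77 (SE 0.07, adjusted p = 2.77e-05), Acta2, smooth muscle actin, by 0.67 and Zeb2, a transcription factor of epithelial-mesenchymal transition, by 0.58. The Acta2 call was lost without probe sets that may hybridise to several transcripts, and those for Acta2, Zeb2 and, in other lists, Chrna3, Tgfb1 and Smad3 when all probe sets of the gene were averaged. In the TGF-beta list 5 of 24 members rose, among them Tgfb1 (0.83, adjusted p = 0.00173), Smad3 (0.50, adjusted p = 0.00506) and the repressor Tgif1 (0.53, adjusted p = 0.00123), but the list itself was not called (camera adjusted p = 0.127).

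The 10 largest rises in siMyT1 among genes whose arrays did not overlap with control were those of Ptgr1, Mrap, Insl6, Prkg2, Dock10, Anxa1, Sparc, Pbxip1, Il33 and Milr1, with log2 fold changes from 1.34 to 1.58. Ptgr1, a prostaglandin reductase, rose from 1.46 ± 0.27 to 4.73 ± 0.59 units (adjusted p = 2.62e-05). Anxa1, an annexin, rose from 0.349 ± 0.075 to 1.27 ± 0.26 and Il33, an alarmin cytokine, from 0.186 ± 0.063 to 0.778 ± 0.014, levels close to the pseudocount in control. After Myt1, the largest falls were those of Atp5mpl, Tubg1, H1f7, Gp6, Scrt1, Rnf112, Nap1l5, Crispld2 and Hmgcll1. Atp5mpl, a small ATP synthase subunit, fell from 17.6 ± 1.6 to 4.78 ± 0.62 (log2 fold change -1.84, SE 0.09, adjusted p = 6.41e-07) and Tubg1, gamma-tubulin, from 12.3 ± 0.37 to 5.68 ± 0.55 (-1.09, adjusted p = 4.67e-06). Scrt1, a neural zinc finger repressor, fell by 1.04 (adjusted p = 0.000164) and Nap1l5, an imprinted gene, by 0.96 (adjusted p = 2.10e-05). Leaving out single arrays ended the calls for H1f7 (siControl replicates 1 and 2, siMyT1 replicates 1 and 2; adjusted p up to 0.130), Gp6 (any siControl replicate, siMyT1 replicates 2 and 3; up to 0.124) and Crispld2 (siControl replicate 2, siMyT1 replicates 2 and 3; up to 0.0726). Crispld2 turned to a log2 difference of 0.13 without probe sets that may hybridise to several transcripts. Among LSD1 complex members and partners, St18, a paralogue of Myt1, rose by 1.03 (SE 0.14, adjusted p = 0.000911) and Phf21a, a reader of unmethylated H3K4 in the complex, by 0.42 (adjusted p = 0.00345), the latter call being lost when all its probe sets were averaged. Gadd45a, a stress-induced growth arrest gene, rose by 1.06 (adjusted p = 8.28e-06) and Klf4 by 0.68 (adjusted p = 0.000515).

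In all, 929 genes were higher and 415 lower in siMyT1 than in siControl, with 297 and 91 at least 1.5-fold changed. The share of calls that were higher, 69.1%, was 55.7% after quantile normalization (1369 higher and 1091 lower) and 56.7% after median centring (652 and 498). Only median centring gave fewer rises. Groups did not overlap for 24.0% of all genes, where chance gives 10%. Camera called the neuronal (adjusted p = 7.64e-08), neuroblastoma (adjusted p = 0.000509) and cholesterol lists (adjusted p = 6.86e-09) down and the mesenchymal list up (adjusted p = 0.0131), and lost all 4 calls with an estimated correlation (adjusted p = 0.876, and 0.879 for the neuroblastoma list). The call of the list Mesenchymal and fibroblast markers, siMyT1 vs siControl, was also lost when all probe sets of a gene were averaged (adjusted p = 0.0843) and without probe sets that may hybridise to several transcripts (adjusted p = 0.0534). Its camera adjusted p ranged from 0.00105 to 0.876 over the alternatives for which camera was run. Fry called the mesenchymal list in this direction (adjusted p = 0.0277) and not the neuronal (adjusted p = 0.127), neuroblastoma (adjusted p = 0.262) or cholesterol list (adjusted p = 0.111). Without siMyT1 replicate 2, the array with the highest median, 419 genes were higher and 274 lower, and the counts were 433 and 215 without siControl replicate 1, 428 and 309 without siControl replicate 3, 439 and 267 without siMyT1 replicate 3, 779 and 217 without siControl replicate 2, and 1174 and 275 without siMyT1 replicate 1. The ratio of 3' to 5' actin control probe sets was 1.11 ± 0.0049 in siMyT1 and 1.17 ± 0.017 in siControl. That of Gapdh differed in the other direction, at 0.796 ± 0.0082 in siMyT1 and 0.785 ± 0.0092 in siControl.

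After siLSD1, more members rose than fell in the neuronal and neuroblastoma lineage lists, and more fell than rose in the lists of mitosis and DNA replication. Camera called these 4 lists, and none of the calls held with the correlation estimated (adjusted p = 0.876 with an estimated correlation for each). Of 38 neuronal genes 9 rose and 1 fell, and adjusted over the list alone 13 were higher and 1 lower. The rises included the neural adhesion gene L1cam (log2 fold change 0.57, SE 0.08, adjusted p = 0.000372), the neuronal tubulin Tubb3 (0.42, adjusted p = 0.000678), the secretogranin Scg2 (0.40, adjusted p = 0.00165) and Gap43, a growth cone protein (0.36, adjusted p = 0.0038). Of 22 neuroblastoma lineage genes 7 rose and 1 fell, namely Hand2, which also fell in siMyT1. Adjusted over the list alone, 9 were higher and 1 lower. Slc18a2 rose from 4.92 ± 0.11 to 10.1 ± 0.060 (log2 fold change 1.01, SE 0.07, adjusted p = 1.37e-06) and Ngfr, the low-affinity neurotrophin receptor, from 12.3 ± 0.95 to 24.9 ± 3.1 (SE of the log2 fold change 0.10, adjusted p = 3.76e-05). Mycn, the oncogene amplified in aggressive neuroblastoma, rose by 0.89 (adjusted p = 4.95e-05) and Gata2, a transcription factor of the sympathoadrenal lineage, by 0.62 (adjusted p = 0.000396).

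In the mitosis list 14 of 25 members fell and 0 rose, and 16 were lower adjusted over the list alone. Mad2l1, a spindle checkpoint protein, fell by 0.77 (SE 0.09, adjusted p = 0.000162), the kinesin Kif11 by 0.61 (adjusted p = 0.00125) and the proliferation marker Mki67 by 0.42 (adjusted p = 0.00109). Of 30 genes of DNA replication and the G1/S transition 13 fell and 1 rose, with 16 lower and 1 higher adjusted over the list alone. E2f2, a transcription factor of S-phase genes, fell from 7.32 ± 0.84 to 1.93 ± 0.25 (log2 fold change -1.82, SE 0.11, adjusted p = 1.11e-06). Cdc45 and Mcm4, parts of the replicative helicase, fell by 0.89 (adjusted p = 3.09e-05) and 0.60 (adjusted p = 6.42e-05). Ccnd1, which encodes cyclin D1, was the member that rose (0.64, SE 0.06, adjusted p = 3.44e-05). Kif11 and E2f2 fell in siMyT1 as well (-0.50, adjusted p = 0.0081, and -0.49, adjusted p = 0.015). There 0 mitosis members and 4 replication members rose. The E2f2 call in siMyT1 was lost without siControl replicate 1 or 2 or siMyT1 replicate 2 (adjusted p up to 0.0717).

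The 10 largest rises after siLSD1 were those of Itgb4, Fam163a, Npy, Pirt, Gpr12, Agtr1a, Ctla2a, Rasl11a, Tmcc3 and Abcc3, with log2 fold changes from 1.23 to 1.72. Npy, the neuropeptide of sympathetic neurons, rose from 0.627 ± 0.084 to 2.40 ± 0.17 (adjusted p = 0.00013), Agtr1a, an angiotensin receptor, from 1.71 ± 0.070 to 5.40 ± 0.68 (adjusted p = 8.46e-06) and Itgb4, an integrin subunit, from 0.286 ± 0.038 to 1.40 ± 0.26 (adjusted p = 6.33e-05). After Kdm1a, the largest falls were those of Egr1, E2f2, Klf12, Gna11, Slc35f5, Pcgf5, Ccdc34, Rad51d and Mybl2. Egr1, an immediate early transcription factor, fell from 8.37 ± 1.3 to 1.56 ± 0.075 (log2 fold change -2.27, SE 0.19, adjusted p = 8.06e-06). Gna11, a G protein alpha subunit, fell by 1.48 (adjusted p = 2.07e-07), Pcgf5, a Polycomb group protein, by 1.45 (adjusted p = 1.11e-06) and Mybl2, a transcription factor of cycling cells, by 1.35 (adjusted p = 2.41e-05). In the list of 19 immediate early genes 4 rose, among them Dusp6 (0.50), and 4 fell, Egr1 and Klf4 (-0.58) among them. Idi1, an enzyme of isoprenoid synthesis, fell by 1.23 (adjusted p = 3.40e-06), while the cholesterol list was not called (2 of 20 lower, 1 higher; camera adjusted p = 0.205). St18 rose by 0.92 (adjusted p = 0.00117), and Rcor3, a CoREST family member, fell by 0.45 (adjusted p = 0.000524). The calls for Rcor3 and Mycn were lost when all probe sets of the gene were averaged.

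Compared with siControl, 721 genes were higher and 894 lower in siLSD1, with 203 and 265 at least 1.5-fold changed. The share of higher calls, 44.6%, was 50.8% after quantile normalization (1421 higher and 1375 lower) and 66.3% after median centring (1101 and 561), so both scalings turned the majority. Groups did not overlap for 26.8% of all genes, against 10% by chance. Camera called the neuronal (adjusted p = 9.47e-06) and neuroblastoma lists (adjusted p = 9.87e-05) up and the mitosis (adjusted p = 2.15e-09) and DNA replication lists (adjusted p = 1.16e-09) down, and lost all 4 calls with an estimated correlation (adjusted p = 0.876 for each). Fry called the mitosis (adjusted p = 0.0388) and replication lists (adjusted p = 0.0194) in this direction and not the neuronal (adjusted p = 0.139) or neuroblastoma list (adjusted p = 0.0545). Leaving out 1 array gave 431 higher and 536 lower genes without siControl replicate 1, 712 and 527 without siControl replicate 2, 454 and 802 without siControl replicate 3, 447 and 767 without siLSD1 replicate 1, 731 and 585 without siLSD1 replicate 2, and 443 and 523 without siLSD1 replicate 3. The majority thus turned without siControl or siLSD1 replicate 2. On the same arrays, 18S ribosomal control probe sets averaged 1.48 ± 0.27 units in siLSD1 and 2.29 ± 0.65 in siControl, and the B1 repeat control 122 ± 2.3 and 108 ± 4.8, differences that did not pass the test.

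**Figure D2:**
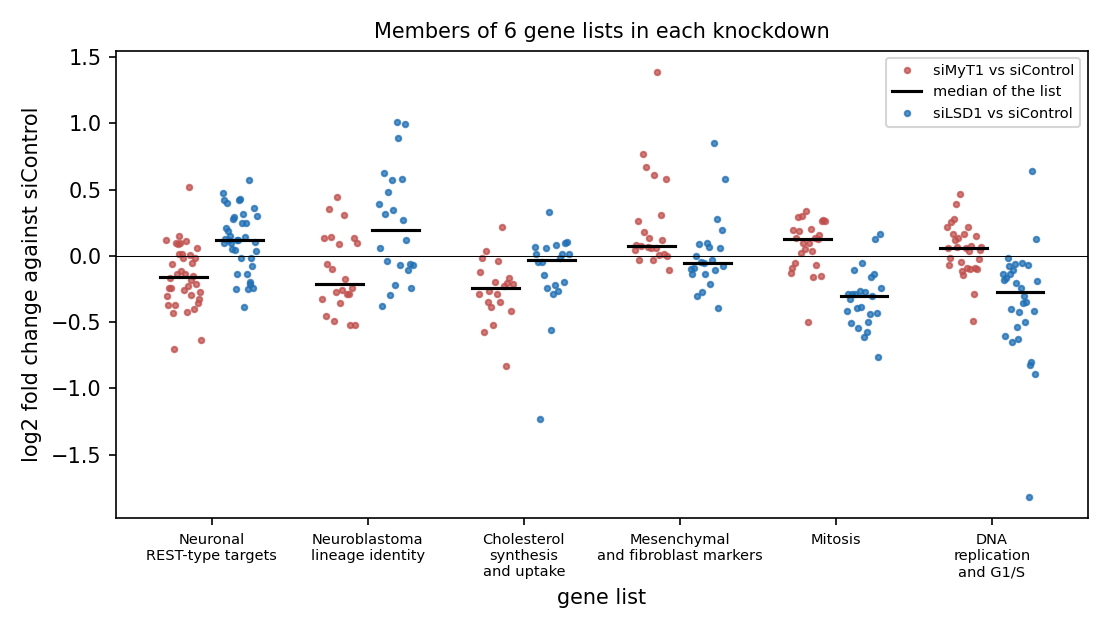
Log2 fold changes against siControl (vertical axis) of the members of 6 gene lists (horizontal axis) in siMyT1 (red) and siLSD1 (blue); each point is a gene and each black line the median of the list. The neuronal median was -0.16 in siMyT1 and 0.12 in siLSD1, the neuroblastoma median -0.21 and 0.20, and the mitosis median 0.13 and -0.30.

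The direct comparison of the knockdowns uses the control arrays only for the shared estimate of spread. In it, more neuronal and lineage list members were lower than higher in siMyT1, and more cell cycle list members were higher than lower. Of 38 neuronal genes 18 were lower in siMyT1 than in siLSD1 and 1 higher, or 21 and 2 adjusted over the list alone. Of 22 neuroblastoma genes 9 were lower and 1 higher, or 11 and 2 adjusted over the list alone. Slc18a2 measured 3.80 ± 0.16 in siMyT1 and 10.1 ± 0.060 in siLSD1 (log2 difference -1.37, SE 0.07, adjusted p = 8.32e-08), Ngfr differed by -1.28, Mycn by -1.14, Chgb by -0.86 and Gap43 by -0.72. Myt1l, a neuronal paralogue of Myt1, was lower by -1.02 (SE 0.12, adjusted p = 6.64e-05). In the mitosis list 15 of 25 members were higher in siMyT1 and 0 lower (21 and 0 adjusted over the list alone), with Mad2l1 at 1.03 and Bub1 at 0.84, and in the replication list 21 of 30 were higher and 1 lower (22 and 1 adjusted over the list alone), with Cdc6 at 1.04 and Cdc45 at 0.87.

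Besides Kdm1a, the largest excesses of siMyT1 over siLSD1 were those of Egr1, Tnnt2, Insl6, Pdgfc, Anxa1, Cxcl10, Herc6, Lama2 and Capn6, with log2 differences up to 1.95. Pdgfc, a growth factor of mesenchymal cells, measured 4.32 ± 0.28 in siMyT1, 1.23 ± 0.21 in siLSD1 and 3.19 ± 0.34 in siControl. Besides Myt1, the largest deficits were those of Gpr12, Atp5mpl, Nap1l5, Pirt, Clu, Adgra1, Npy, Ampd3 and Tesc, from -1.40 to -1.93. Tesc, a calcium-binding protein, measured 14.5 ± 0.94 in siMyT1, 38.7 ± 1.8 in siLSD1 and 19.1 ± 0.38 in siControl. Of 28 interferon response genes 7 were higher in siMyT1 and 1 lower, with Cxcl10 at 1.59 and Eif2ak2, the kinase PKR, at 0.68, but the list was not called (camera adjusted p = 0.293). In the PI3K signalling list 1 of 25 members was higher and 3 lower, namely the regulatory subunit Pik3r3 (-1.11, adjusted p = 3.31e-05) and the insulin receptor substrates Irs2 (-0.57) and Irs1 (-0.53), and camera did not call it (adjusted p = 0.189).

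Altogether 2402 genes were higher and 1013 lower in siMyT1 than in siLSD1, with 754 and 292 at least 1.5-fold different, and groups did not overlap for 33.0% of all genes, against 10% by chance. Without siMyT1 replicate 2 or 3, 1524 and 1563 genes were higher. Of 64 control probe sets, 6 were higher and 1 lower in siMyT1 than in siLSD1, with limma p-values adjusted over all probe sets. Against siControl, 0 were called in siMyT1, and 0 were higher and 3 lower in siLSD1. The share of higher calls, 70.3%, was 55.6% after quantile normalization (2409 higher and 1922 lower) and 42.4% after median centring (1247 and 1694), which moved the median of all genes by -0.13. Relative to the median of all genes, the 60 members of the neuronal and neuroblastoma lists together had a median of -0.33, and -0.32 after quantile normalization. Camera called the neuronal (adjusted p = 4.17e-12), neuroblastoma (adjusted p = 1.16e-07), axon guidance (adjusted p = 0.016) and cholesterol lists (adjusted p = 0.0131) down and the mitosis (adjusted p = 2.73e-08) and replication lists (adjusted p = 7.47e-09) up. None held with the correlation estimated (adjusted p = 0.876 with an estimated correlation, and 0.999 for the cholesterol list). Fry called the neuronal (adjusted p = 0.0194), neuroblastoma (adjusted p = 0.0194), mitosis (adjusted p = 0.0237) and replication lists (adjusted p = 0.0194) in the same directions, and not the axon guidance (adjusted p = 0.374) or cholesterol list (adjusted p = 0.476). Fry also called the mesenchymal (6 of 22 higher, 1 lower; adjusted p = 0.0240) and immediate early lists (5 of 19 higher, 3 lower; adjusted p = 0.0253) up, which camera did not (adjusted p = 0.127 for each). Of 27 genes of amino acid starvation and ER stress 7 were higher and 0 lower, or 9 and 0 adjusted over the list alone. Neither camera (adjusted p = 0.127) nor fry for 1 direction (adjusted p = 0.207) called the list. Fry for change in either direction did (adjusted p = 0.000577). In each comparison that form of fry also called the neuronal, neuroblastoma, cholesterol and axon guidance lists. It called lists that camera did not call as well, such as p53 targets (fry adjusted p = 2.80e-07 in the direct comparison). In the axon guidance list 6 of 39 members were lower and 1 higher, also adjusted over the list alone, and the median was -0.02. In the cholesterol list 5 of 20 were lower, among them Srebf2 (-0.85) and Dhcr7 (-0.85), and 3 higher, among them Idi1 (0.66), or 6 and 3 adjusted over the list alone. The call of the list Cholesterol synthesis and uptake, siMyT1 vs siLSD1, was lost without siLSD1 replicate 1, where the adjusted p was 0.0684.

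Across genes, the changes of the knockdowns coincided only in part. In both knockdowns 173 genes were higher and 70 lower than control, against 36.8 and 20.4 expected of independent lists and 0 in simulations of unchanged groups against the same controls. The former value leaves out the shared controls and the latter the effects, so neither is the overlap to be expected here. The genes higher in both included Milr1, Nek3, Acp1, Tm4sf1, Prkg2, Bst2, Arhgdib, Ptgr1, St18 and Sparc. Acp1, a low molecular weight phosphatase, rose from 18.4 ± 0.16 to 45.7 ± 2.4 in siMyT1 and 39.4 ± 3.3 in siLSD1, and Nek3, a NIMA-related kinase, from 1.70 ± 0.082 to 4.03 ± 0.57 and 3.98 ± 0.30. Bst2, the interferon-induced restriction factor tetherin, rose by 1.10 and 0.99. The genes lower in both included H1f7, Crispld2, Rgs4, Bend4, Tspyl4, Particl, Cyp2c39, E2f8, Idi1 and Lor. Bend4 fell by 0.76 in siMyT1 and by 1.17 in siLSD1, and Rgs4, a regulator of G protein signalling, by 0.78 and 0.90. Leaving out single arrays ended calls of some of these genes in both knockdowns. Without siControl replicate 1, among other arrays, this held for Tm4sf1 (adjusted p up to 0.0935 in siMyT1 and 0.0534 in siLSD1), H1f7 (0.130 and 0.0853), Particl (0.113 and 0.0523) and Lor (0.0929 and 0.160). Without siControl replicate 2 it held for Crispld2 (0.0726 and 0.0883) and, in siMyT1, E2f8 (0.0719). The calls for Tspyl4 were lost when all its probe sets were averaged. The counts of 173 and 70 fell to 80 and 32 without siControl replicate 1, 163 and 23 without siControl replicate 2, 79 and 51 without siControl replicate 3, 104 and 41 without siMyT1 replicate 2, 93 and 44 without siMyT1 replicate 3, 111 and 61 without siLSD1 replicate 1, and 101 and 37 without siLSD1 replicate 3, while 40 were lower in both without siMyT1 replicate 1. Of the shared genes 47 of the 173 and 19 of the 70 also differed between the knockdowns in the direct comparison.

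A further 54 genes were higher in siMyT1 and lower in siLSD1 (45.7 expected of independent lists), and 54 were lower in siMyT1 and higher in siLSD1 (16.5 expected). All 108 differed in the direct comparison, but their selection fixed this outcome, so it is no separate evidence. Opposite changes from the same control arrays add up in the difference between the knockdowns, at the same SE for a gene. By a rule set after the values were seen, the 5 of these genes with the largest smaller change were named in each direction. The latter were Clu (-0.76 in siMyT1, 0.86 in siLSD1), Nap1l5 (-0.96 and 0.74), Ache (-0.55 and 0.57), Myt1l (-0.51 and 0.51) and Ndrg4 (-0.47 and 0.51), and the former Herc6 (0.74 and -0.77), Tmem178 (0.68 and -0.74), Triobp (0.74 and -0.66), Oxr1 (0.61 and -0.87) and Naalad2 (0.69 and -0.59). Leaving out single arrays, among them siControl replicate 1 or 3, ended calls in both knockdowns for Ache (adjusted p up to 0.139 in siMyT1 and 0.103 in siLSD1), Myt1l (0.0722 and 0.0739), Tmem178 (0.157 and 0.109) and Naalad2 (0.0642 and 0.123), and in siMyT1 for Herc6 (0.0515). With probe sets averaged, Myt1l was called in neither knockdown and Naalad2 not in siMyT1, and without probe sets that may hybridise to several transcripts Naalad2 was called in neither. Of 993 genes called in siMyT1 and not in siLSD1, 739 differed between the knockdowns by the direct test, as did 989 of 1264 called in siLSD1 and not in siMyT1. Over all 18193 genes the direct test called 3415. The selection of these genes used the same knockdown arrays and favours such a difference, so these shares are no separate evidence either. Over all 18193 genes, which are not independent replicates, the log2 fold changes correlated at r = 0.264. The value simulated for unchanged groups sharing the control arrays was 0.501. Effects of 1 knockdown alone lower r and were absent from the simulation, so the lower r does not show less agreement than without effects. The covariance of the log2 fold changes was 0.0162 against a simulated mean of 0.0148, a difference of 0.00139, and a simulated maximum of 0.0156. The 3 control arrays were not split, since 1 knockdown would have kept a single control, and part of the overlap in the same direction may come from them. By the F-test 3539 genes differed among the 3 groups.

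**Figure D3:**
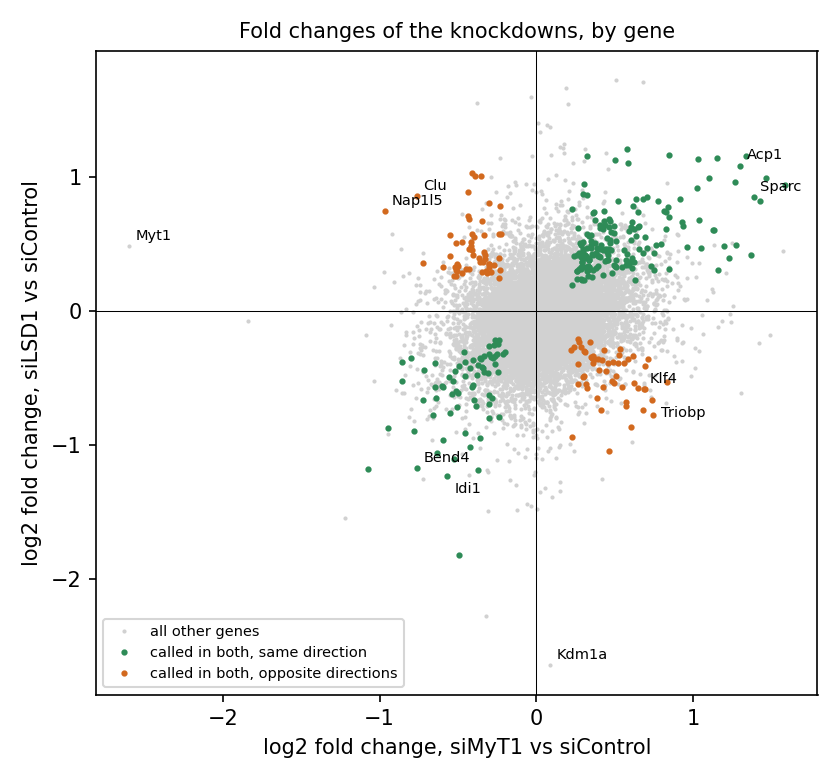
Log2 fold change against siControl in siMyT1 (horizontal) and siLSD1 (vertical) of all 18193 genes, each point a gene; green points were called in both knockdowns in the same direction (173 higher, 70 lower), orange points in opposite directions (54 and 54), and grey points are all others. Myt1 and Kdm1a lie far out on the axis of their own siRNA, at -2.60 and -2.64.

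Beside the mesenchymal markers, the lists of markers of other cell types were not called by camera in any comparison, and 0 of 15 macrophage and microglia markers passed the test (camera adjusted p = 0.973, 0.848 and 0.848 in siMyT1, siLSD1 and the direct comparison). In siMyT1 against control, 0 of 13 astrocyte markers (0.876) and 1 of 18 oligodendrocyte markers (0.876), Tspan2, passed the test. Of 15 ribosomal protein genes 0 passed in any comparison (list adjusted p = 0.973, 0.998 and 0.986). In siLSD1 the astrocyte transcription factor Sox9 rose by 0.74 and 1 other astrocyte marker, Ndrg2, fell by 0.42, a call lost without any of 8 arrays, siControl replicate 1 included (adjusted p up to 0.177; list adjusted p = 0.973), and the oligodendrocyte list had no called member (0.848). For the other lists that camera did not call in siMyT1 against control, the adjusted p was 0.0708 for the interferon response, 0.115 for amino acid starvation and ER stress, 0.127 for axon guidance, immediate early genes and PI3K signalling, 0.367 for hypoxia and glycolysis and for the siRNA machinery, 0.45 for mitochondrial energy metabolism, 0.552 for mitosis, 0.782 for the Notch pathway, 0.792 for DNA replication, 0.952 for p53 targets and 0.973 for the LSD1 complex. For those not called in siLSD1 against control it was 0.127 for TGF-beta signalling, 0.316 for axon guidance, 0.492 for the LSD1 complex, 0.603 for p53 targets, 0.634 for immediate early genes, 0.672 for mesenchymal markers, 0.782 for PI3K signalling, 0.848 for hypoxia and for amino acid starvation, 0.973 for mitochondrial metabolism and for the siRNA machinery, 0.986 for the Notch pathway and 0.998 for the interferon response. The direction of the camera test, which compares a list with all other genes, differed from the sign of both its median and its mean for p53 targets and the oligodendrocyte and macrophage markers in siMyT1. It did so in siLSD1 for the interferon response, hypoxia, mitochondrial metabolism, the siRNA machinery and the astrocyte, macrophage and ribosomal lists, and in the direct comparison for the oligodendrocyte and macrophage markers. It differed from 1 of them for the LSD1 complex in each comparison, for astrocyte markers in siMyT1 and the direct comparison, for PI3K signalling in siLSD1 and the direct comparison, and for axon guidance and mesenchymal markers in siLSD1. Among 100 groupings of the 9 arrays, the real one included, 21 gave at least the 14 list calls of the real groups, and the median of the other groupings was 9.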

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

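The tests of scaling, shared controls, single arrays and cell cycling for the neuronal genes, of scaling for the excess of rises, and of the share of common genes that differ between the knockdowns were chosen only after the result was seen. Among 9160 probe sets without a gene in the annotation, which enter no comparison between groups above, 59 were higher and 18 lower in siMyT1 than in siControl, and 67 were higher and 67 lower in siLSD1. Among 932 probe sets with several genes, 16 were higher and 17 lower in siMyT1, and 17 were higher and 37 lower in siLSD1. In siMyT1 against siLSD1, 176 without a gene were higher and 109 lower, and 80 and 34 with several genes. Among the 18193 named genes, 929 were higher and 415 lower in siMyT1, and 721 and 894 in siLSD1. These probe sets were thus called less often than named genes, with p-values adjusted over all probe sets instead of all genes.

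The 60 neuronal and neuroblastoma list members had a median log2 difference of -0.24 between siMyT1 and siLSD1. Median centring shifts all genes of an array equally, so it could not move the median relative to all genes (-0.3278). Under quantile normalization, which could, that median was -0.321. Scaling as the whole cause was excluded on that test alone. Chance values of the control arrays do not enter this difference, so the direct comparison could not test them. The control arrays act there only through the shared estimate of spread. In it 27 members were lower and 2 higher, with medians of -0.17 in siMyT1 and 0.12 in siLSD1 against control. As the cause, 1 aberrant array was excluded, since the median nearest to 0 with an array left out was -0.2009. A link to slower cell cycling stays open. In siMyT1, the only knockdown used in that test, the 55 mitosis and replication genes had a median of 0.0174 relative to all genes. It ranged from 0.0119 to 0.0434 with an array left out, above 0, but neither list was called. In siLSD1 the mitosis median was -0.30 and the replication median -0.27, and camera called both lists down, though not with an estimated correlation. By sign alone, 18 of 38 neuronal and 10 of 22 neuroblastoma members were lower in siMyT1 and higher in siLSD1 than in siControl. The opposite list medians therefore do not hold for each member. Opposite effects of the 2 siRNAs on part of these genes may be a biological explanation, which the design does not separate from off-target effects of single siRNAs.

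More genes were higher than lower after siMyT1. Array scaling stays open as a cause. Under quantile normalization 55.65% of calls were higher against 69.1% as deposited, but the higher calls increased from 929 to 1369 and the lower ones from 415 to 1091, and only median centring gave fewer rises (652 higher and 498 lower). A raised background among dim probe sets stays open, because 62.82% of the 632 called genes among the brightest 25% of genes were higher, between the bounds set in advance. No biological explanation was tested.

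Of the 243 genes changed in the same direction in both knockdowns, 66 also differed between the knockdowns, as did 3415 of all 18193 genes. An effect of the control siRNA or control arrays alone does not allow such a difference. It may still underlie the part of the change that the knockdowns share in these 66. For the other 177, a control effect alone stays open, since no untreated group was analysed here. The 14.12% of them with an unadjusted p below 0.05 in the direct comparison decides nothing, because these genes were chosen as not called in that comparison. A response common to any active siRNA may be another explanation, untested for the same reason.

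With 10 splits of 6 arrays, the splits are too few for a share under 0.05 in each comparison of a pair of groups. The real split gave 1344 genes in siMyT1 against siControl, 1615 in siLSD1 against siControl and 3415 in siMyT1 against siLSD1, each reached by 1 of 10 splits, with 0 genes in the highest other split of each. Chance can be excluded for the F-test only in the sense that the arrays were not interchangeable. There 1 of 100 groupings of the 9 arrays, the real one, reached 3539 genes and the highest other gave 1010. Chance differences between cultures are not excluded, because the labels do not say whether the replicates of a group came from separate cultures. For the 173 genes higher and the 70 lower in both knockdowns, each reached by 3 of 100 groupings, chance can be excluded only in the same sense. That the arrays were not interchangeable does not test an overlap of the knockdowns. The highest other groupings gave 426 and 265, and both groupings above the real one kept the siLSD1 arrays together as the reference against mixtures of the rest, which points to a structure of the samples. Chance cannot be excluded for the number of list calls, because 21 of 100 groupings gave at least 14, with 18 as the highest other.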

How the results depend on the processing

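The constant behind the main pseudocount was chosen only after the values were seen. The pseudocount of 32 on deposited units, the literal form of the rule fixed in advance, and the floor of 0.01 became alternatives only after the result was seen. All 14 list calls kept their direction and side of the threshold under both scalings, and 0 held with an estimated correlation. The mesenchymal call in siMyT1 was also lost with averaged probe sets and without _x_at and _s_at probe sets, and the cholesterol call in siMyT1 against siLSD1 without siLSD1 replicate 1. Of 309 called results of named genes, 109 lost the call under some alternative, 70 of them with an array left out. Those reversed were Crispld2 in siMyT1 (0.1549 with pseudocount 1, 0.129 without _x_at and _s_at probe sets, 0.1559 with the floor) and Acta2, siMyT1 vs siLSD1 (-0.0281 without those probe sets). The cause of the shifts below was not tested, except where fewer arrays or a stricter threshold is the alternative itself. Dim genes are limited by background, and the correlation of the knockdowns was 0.3978 with pseudocount 1, 0.1957 with 100, 0.1471 with 32 on deposited units (114 genes higher in both), 0.4049 with the floor and 0.213 with the dim filter (111 lower in both). Camera was not run with changed variance models, with array weights, on fits of the compared groups alone or on single probe sets.

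Quantile normalization gave 1091 lower genes in siMyT1, 1421 higher and 1375 lower in siLSD1, 1922 lower in siMyT1 against siLSD1, and 376 higher and 235 lower in both. Median centring gave 1101 and 561 in siLSD1 and 1247 and 1694 in the direct comparison. Averaging probe sets gave 618 and 244 in siMyT1, 455 higher in siLSD1, and 97 and 38 in both, and testing every probe set gave 1590 lower in the direct comparison. Without the variance trend the counts were 562 and 202 in siMyT1 and 91 and 33 in both. Array weights gave 1317 and 1647 in siLSD1, 335 and 122 in both and a correlation of 0.2856. At 1.5-fold the counts were 297 and 91, 203 and 265, 754 and 292, 847 by the F-test, and 36 and 9 in both. Replicate numbers did not pair the arrays (deviations correlated at -0.0264 to 0.0374 over 9 pairs), and the number as a block gave 649 and 285, 567 and 691, 2048 and 875, and 110 and 35 in both. With 1 array left out, siMyT1 had 419 to 1174 higher and 215 to 441 lower genes, siLSD1 431 to 765 and 523 to 953, and the direct comparison 1524 to 2894 and 704 to 1045. The F-test gave 2430 to 3716 genes, 79 to 195 were higher and 23 to 61 lower in both, the correlation was 0.2244 to 0.3474, and 14 to 17 lists were called.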

Other observations

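The added lists of YAP and TAZ targets, mesenchymal neuroblastoma state factors, imprinted genes and clustered protocadherins were chosen only after the results above were seen. Their predictions were written before the list results were. Some members also stand on the lists fixed in advance (Ccn2, Fosl1, Sox9, Egr3, Tgfbr2 and Cdkn1c), and Sox9 had been named, so these lists are not independent of the others. The members given here were named after their values were seen. Among 25 targets of YAP and TAZ, transcriptional coactivators that respond to cell tension, 6 were higher and 2 lower in siMyT1 than in siLSD1, with a median of 0.19. Axl, a receptor tyrosine kinase, was higher by 1.16, Myof by 0.92, Crim1 by 0.74 and Ankrd1 by 0.72, and Fjx1 was lower at -0.73. Among 22 clustered protocadherins, adhesion genes of neurons, Pcdhb17 fell by 0.68 in siMyT1 and the list median was -0.11.

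The hypotheses about these lists were not settled by camera over 12 tests. That the YAP and TAZ programme may be higher after siMyT1 than after siLSD1 had an adjusted p of 0.7874, and that mesenchymal state factors may rise after siMyT1 also 0.7874, with 1 of 24 members higher (Ets1, 0.52) and a median of 0.13. That imprinted genes may fall together after siMyT1 had an adjusted p of 0.9521, with Mest higher (0.31), Peg3 lower (-0.25) and a median of 0.06 of the opposite sign to the test. By the prediction written in advance, a median at or above 0 counts against such a fall. For a fall of the protocadherins it was 0.2017.

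The 3 control probe sets of the transferrin receptor were lower in siLSD1 than in siControl, at log2 differences of -0.45, -0.63 and -0.53 (limma adjusted p = 0.00803, 0.0408 and 0.0199). The probe set used for Tfrc itself differed by -0.22 and did not pass the test (adjusted p = 0.0638).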
